A study of Caenorhabditis elegans with 2 samples.

How the data were processed

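ChIP-seq of eGFP-F16B12.6 was measured in whole L1 larvae of C. elegans strain OP114 in 2 biological replicates, which the labels number 1 and 2 and give separate biosamples. The labels state a size range of 150 to 350 and the assemblies ce11 and ce10. The authors deposited 8 peak lists, 4 on each assembly. Per the readme notes deposited with the files, each replicate's relaxed list (peaks and background, made as input for an irreproducible discovery rate analysis, IDR) was derived from that replicate's alignments and 1 control file. The pooled relaxed list was derived from both replicates' alignments and a control, and the thresholded list (optimal IDR peaks) from the pooled and both replicate lists. The thresholded list therefore exists only for pooled replicates, while the relaxed lists allow replicates to be compared. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here.

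The deposited lists have 10 columns and no header. Column 7 was read as the caller's signal value, a signal that the authors' caller assigned to each entry and whose scaling is not stated. Column 9 was read as the −log10 q value that the authors' caller gave, from its place in the layout of deposited peak files of this kind. It reached one shared maximum in every thresholded peak, so the signal value was used for ranking. Signal values were used only to describe and rank entries within a list. All 2183 thresholded peaks on ce11 were found in the pooled relaxed list with identical values and were its 2183 strongest entries. The most common width was 250 bp (70.7% of thresholded peaks), so most widths were set by the caller, and the thresholded peaks cover 0.507% of the genome. Read numbers are not given in the sources used here, so no interval based on depth was formed. Intervals on shares treat peaks or genes as independent units, which neighbouring genes are not.

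Entries on ce11 were compared with the WBcel235 sequence and the Ensembl release 115 gene annotation, which use the same coordinates. No entry ran past a chromosome end. No coordinate was converted between assemblies, and ce10 lists were used only for counts, overlaps and ranks. Coordinates are 1-based. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5' end of a protein-coding gene on the 6 nuclear chromosomes (19973 genes), and a gene was called bound when a thresholded summit lay in its window. The comparison set for thresholded peaks was the 27802 pooled relaxed entries that overlapped none of them.

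Replicate overlap was tested with 1000 circular shifts per chromosome. Shares were compared with two-sided Fisher's exact tests, and 95% intervals of odds ratios used the normal approximation on the log scale, with 0.5 added to each cell where one was 0. Shares have Wilson intervals, which cover counting error only. Counts of 0 bound genes in a named list or family are given with the share that 3 counts would be. Values of p under 1e-300 were set to 1e-300. Gene lists (29, defined by gene symbols), non-coding classes (within 500 bp of a summit) and k-mers were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. For k-mers, presence in the 100 bp centred on the summit was compared with presence in the same length centred 200 bp to one side, drawn with a fixed seed, by McNemar's exact (binomial) test. For the comparison at equal G and C content, weaker promoter entries were weighted to the counts of G and C at the strongest summits. Entries around F16B12.6 and unc-119 were counted within 20 kb with exact Poisson intervals.

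The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named F16B12.6 and unc-119, the genes at the 15 strongest thresholded peaks, up to 3 bound members with the highest signal in each list past the threshold and up to 2 in the others, and the 5 k-mers with the lowest p. The 8-base sequences, ACGCAG and the summit sequence at chmp-7 are given in addition and were chosen after their values were seen. Alternatives were other promoter windows, gene assignments, backgrounds, overlap definitions, k-mer windows and lengths, the 1091 strongest peaks, the ce10 lists, and the 2183 strongest entries of a single replicate in place of the thresholded list.

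Computation used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1. The tests were tested on simulated data. In 20 simulated pairs of lists of 2183 peaks with 60% planted as shared, 60.4% were found as shared, and 1 of 20 unrelated pairs was called. With the real 29 lists over 19973 genes and 5 lists raised from 10% to 50% bound, all raised lists were recovered in 20 runs and 2.92% of the unraised lists were called. With a 6-mer planted at 10% of summits, it had the lowest p of 2080, and 5 were called in all, against 1 with no planting. The simulations placed peaks evenly, bound genes independently and gave summits and flanks equal base composition. Their rates of false calls therefore need not hold for the real lists.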

Results

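The data describe where an eGFP-tagged copy of the protein F16B12.6 was recovered on the genome of Caenorhabditis elegans in the first larval stage. F16B12.6 is annotated as a protein with a DUF7747 domain and has no standard gene name. The worms were whole, mixed-sex larvae of strain OP114, which carries a mutant unc-119 allele on chromosome III and the integrated transgene wgIs114. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 2 biological replicates, which make up 1 group, so the comparisons are between replicates, between stronger and weaker entries, and between classes of genes. Each replicate has a relaxed list of 30000 entries, in which peaks and background are ranked together. Both replicates pooled have a further relaxed list of 30000 entries and a thresholded list of 2183 peaks on the ce11 assembly. The number of sequenced reads is not given in the sources used here, so the depth behind each entry is unknown.

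The first question was how far the replicates shared their strongest sites. Of the 2183 strongest entries of replicate 1, 1709 overlapped one of the 2183 strongest of replicate 2 by at least 1 bp, which is 78.3% (95% Wilson interval 76.5 to 80.0%). After circular shifts of the second list along each chromosome the share was 1.09% on average and never above 2.02% (permutation test, 1000 shifts, one-sided p = 0.001, the smallest value they can give). The overlap was 86% among the 100 strongest entries, 90% among 200 and 96.6% among 500, fell to 51.9% at 5000 and was 27.1% at 30000, where shifted lists shared 13.7%. Of the thresholded peaks, 1980 (90.7%) were among the 2183 strongest entries of replicate 1 and 1884 (86.3%) among those of replicate 2. The signal ranks of the 2159 thresholded peaks found in both replicates had a Spearman correlation of 0.823 across peaks. The thresholded list was derived from the pooled and both replicate lists and held the strongest pooled entries. Its peaks were thus selected with the use of both replicates, and this correlation holds only within that selection. It leaves out the thresholded peaks that overlapped no entry of replicate 1 (2 peaks) or of replicate 2 (22 peaks).

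**Figure D1:**
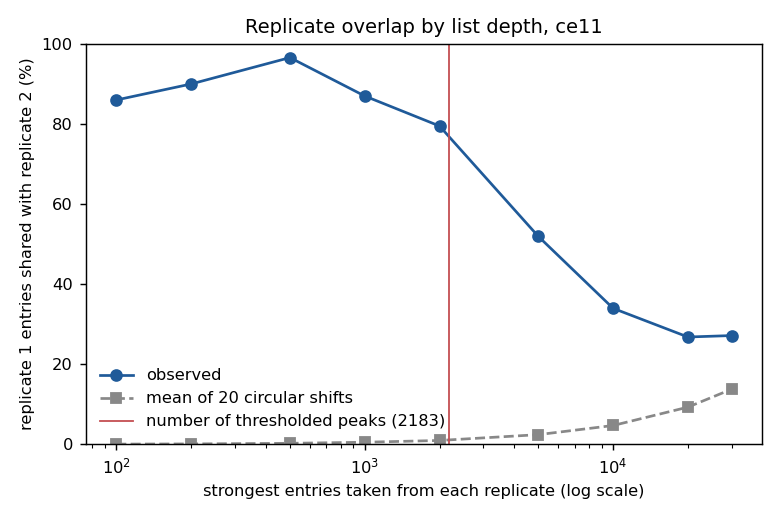
Share of replicate 1 entries that overlap a replicate 2 entry by at least 1 bp (y axis, percent), against the number of strongest entries taken from each replicate (x axis, log scale). Circles are observed shares, squares are means after 20 circular shifts and the vertical line marks the 2183 thresholded peaks; the observed share is 86% at 100 entries, 96.6% at 500 and 27.1% at 30000.

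The strongest peak lay at the promoter of chmp-7, which encodes a relative of the ESCRT-III membrane remodelling proteins. It spanned positions 9054650 to 9054947 of chromosome II (ce11), had its summit upstream of the annotated 5' end (relative position -165 bp) and a signal value of 1543. It ranked 1 in both replicates. The 41 bp centred on its summit, from 9054787 to 9054827, read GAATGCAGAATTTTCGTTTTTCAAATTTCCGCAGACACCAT on the plus strand. The peak ranked second (IV, 3725905 to 3726183, signal 1316) lay between smgl-2, a gene of the nonsense-mediated decay group, and Y37E11AM.2, and the third (IV, 1094229 to 1094503, signal 1248) between the chaperonin subunit gene cct-8 and Y55F3AR.2. The fourth (III, 3456281 to 3456544, signal 1232) was inside C34C12.1, in an annotated 5' UTR 2074 bp downstream of the gene's first 5' end, and was the only one of the 15 strongest with its summit outside a promoter window.

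The other peaks among the 15 strongest lay at promoters of genes with varied products. Peaks 5 and 6 were at citk-2 and F59A6.11 (II, 4999228 to 4999469, signal 1089) and at mrpl-28, a mitochondrial ribosomal protein gene (II, 155986 to 156265, signal 1032). Peak 7 lay between drr-2, a translation initiation factor gene, and set-16, a histone methyltransferase gene (III, 13643580 to 13643866, signal 1014). Peaks 8 to 11 were at spat-2 (signal 999), at maa-1 and C18D11.3 (977), at the Mediator subunit gene mdt-22 (959) and at the vulval development gene lin-36 (959). Peaks 12 to 15 were at the chromodomain gene mrg-1 and the signal peptidase gene spcs-2 (signal 922), the kinase gene wee-1.3 (922), the ESCRT gene vps-37 (920) and the translocon genes sec-61.B and trap-3 (910). All 15 ranked between 1 and 17 in each replicate.

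Thresholded peaks were concentrated at promoters of protein-coding genes. The summit fell in the window from 1000 bp upstream to 200 bp downstream of an annotated 5' end for 1661 of 2183 peaks (76.1%, Wilson interval 74.3 to 77.8%). The same held for 6581 of the 27802 relaxed pooled entries that overlapped no thresholded peak (23.7%, 23.2 to 24.2%), and the window covers 21.5% of the genome. The odds ratio was 10.3 (95% interval 9.26 to 11.4), with a two-sided Fisher's exact p at the smallest value written, 1e-300. The share was 85.5% among the 1091 strongest peaks, with an odds ratio of 19.04. Coding exons outside the windows held 0.504% of thresholded summits against 19.5% of the weaker entries, introns 10.6% against 31.2%, and intergenic sequence 11.7% against 22.4%. The test counts peaks of pooled libraries, not animals.

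Summits lay just upstream of the annotated 5' ends. The median position relative to the nearest protein-coding 5' end was -162 bp (quartiles -352 and -49.5 bp) for thresholded peaks. Of the thresholded summits, 44.1% lay within 200 bp of a 5' end, against 9.26% of the weaker entries. Among summits within 1000 bp, 88.5% were upstream, against 47.9% of the weaker entries. Annotated 5' ends of trans-spliced worm genes often mark the splice acceptor and not the transcription start.

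**Figure D2:**
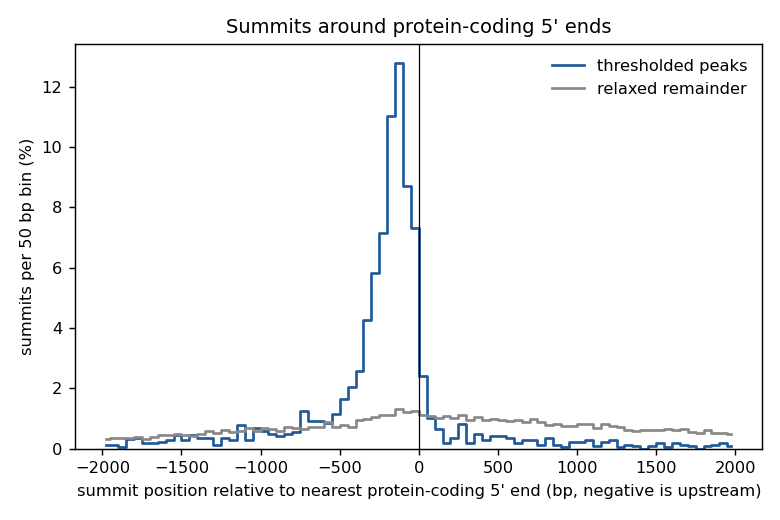
Position of summits relative to the nearest protein-coding 5' end (x axis, bp, negative values upstream), as the percent of summits per 50 bp bin (y axis). The blue line shows the 2183 thresholded peaks, with a median of -162 bp, and the grey line the 27802 relaxed entries that overlap none of them.

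The X chromosome carried fewer thresholded peaks per megabase than each autosome. It held 211 of 2183 (9.67%, Wilson interval 8.50 to 10.98%), against 16.1% of the weaker entries (odds ratio 0.560, 0.484 to 0.647, two-sided Fisher's exact p = 7.50e-17) and 13.7% of protein-coding 5' ends (odds ratio 0.676, 0.583 to 0.783, Fisher's exact p = 6.96e-08). Chromosome III had the highest density, with 499 peaks or 36.2 per megabase, followed by I with 482 (32.0), II with 388 (25.4), IV with 320 (18.3) and V with 283 (13.5). The X chromosome had 11.9 per megabase. Relative to protein-coding genes, a comparison chosen after the data were seen, chromosome V had fewer, with 56.7 peaks per 1000 genes against 77.3 on X and 97.5 on IV, the next lowest. The middle 50% of the chromosomes held 56.8% of the thresholded peaks (54.7 to 58.8%) against 48.7% of the weaker entries (odds ratio 1.38, 1.26 to 1.51, Fisher's exact p = 5.49e-13). Protein-coding 5' ends lay in the middle part at a share of 55.3%, and against these the odds ratio was 1.06 (0.971 to 1.16, Fisher's exact p = 0.196).

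Among the 29 gene lists fixed in advance, those for cytosolic ribosomal proteins, protein breakdown, cell division, respiration and splicing were bound most often. Of 19973 protein-coding genes, 2356 (11.8%) had a thresholded summit in the promoter window, and 9 lists were bound more often than the remaining genes. Among cytosolic ribosomal protein genes 68 of 81 were bound (84.0%, odds ratio 40.2, 22.2 to 73.0, adjusted Fisher's exact p = 3.63e-49), with the strongest peaks at rpl-5 (signal 699), rpl-35 (337) and rpl-3 (333). Of 33 proteasome subunit genes 23 were bound (69.7%, odds ratio 17.4, 8.25 to 36.5, adjusted Fisher's exact p = 8.31e-14), led by rpn-11 (739), rpt-6 (717) and rpt-3 (495). Of 55 cell cycle and DNA replication genes 32 were bound (58.2%, odds ratio 10.5, 6.15 to 18.03, adjusted Fisher's exact p = 1.88e-15), led by the kinase gene cdk-11.2 (589), the sliding clamp gene pcn-1 (515) and the replicative helicase gene mcm-4 (500). With each summit given only to the nearest 5' end, 39 of the 81 ribosomal protein genes were bound (48.1%, odds ratio 9.16), a smaller share than for proteasome (57.6%, 13.3) and cell cycle genes (50.9%, 10.2). Among the 8186 genes with any relaxed entry in their window the odds ratios of the 3 lists were 24.7, 8.20 and 6.68, and with the 1091 strongest peaks that of the proteasome list was 11.5.

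Respiratory chain and ATP synthase genes were bound in 25 of 44 cases (56.8%, odds ratio 9.93, 5.46 to 18.1, adjusted Fisher's exact p = 4.73e-12), with signals of 357 at atp-4, 330 at asg-1 and 304 at cox-6C. Splicing factor genes were bound in 24 of 47 cases (51.1%, odds ratio 7.87, 4.44 to 13.97, adjusted Fisher's exact p = 2.41e-10), led by snr-6 (614), prp-31 (330) and snr-7 (269.8). Aminoacyl-tRNA synthetase genes were bound in 14 of 32 cases (43.8%, odds ratio 5.84, 2.90 to 11.8, adjusted Fisher's exact p = 1.52e-05), led by nars-1 (415), qars-1 (352) and sars-1 (321). Genes for heat-shock proteins and chaperonins were bound in 21 of 60 cases (35.0%, odds ratio 4.05, 2.38 to 6.90, adjusted Fisher's exact p = 6.93e-06), led by cct-8 (1248), cct-5 (474) and dnj-10 (317). With the nearest 5' end this last list no longer passed the threshold (odds ratio 1.49), and the respiratory odds ratio was 5.57. Among genes with any relaxed entry the odds ratios were 4.16 for respiratory, 3.74 for splicing and 2.49 for heat-shock genes, all past the threshold. That of the respiratory list was 6.42 with the 1091 strongest peaks. Without candidates for internal operon genes it was 15.9, and 9.16 for the synthetases. This setting kept 14214 of 19973 genes and also dropped many chemoreceptor genes (873 of 1309 kept), so the change was not read as an effect of operons.

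Autophagy genes and genes of the lysosome and its proton pump were also bound more often than the remaining genes, with calls that depended on the setting. Of 30 autophagy genes 10 were bound (33.3%, odds ratio 3.75, 1.75 to 8.02, adjusted Fisher's exact p = 0.00319), with high signals at epg-8 (797), atg-3 (556) and epg-7 (467). Of 58 lysosome and V-ATPase genes 14 were bound (24.1%, odds ratio 2.39, 1.31 to 4.36, adjusted Fisher's exact p = 0.0122), led by vha-10 (269), lmp-1 (264) and cup-14 (73.3). Neither list passed the threshold with only the 1091 strongest peaks (odds ratios 2.10 and 1.88) or among genes with any relaxed entry (1.91 and 1.65). Autophagy genes had higher odds ratios with the nearest 5' end (13 of 30, 7.45) and with a 2000 bp upstream window (15 of 30, 5.90). The lysosomal list also missed it with a 500 bp upstream window (1.89) and with replicate 2 alone (2.05).

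**Figure D3:**
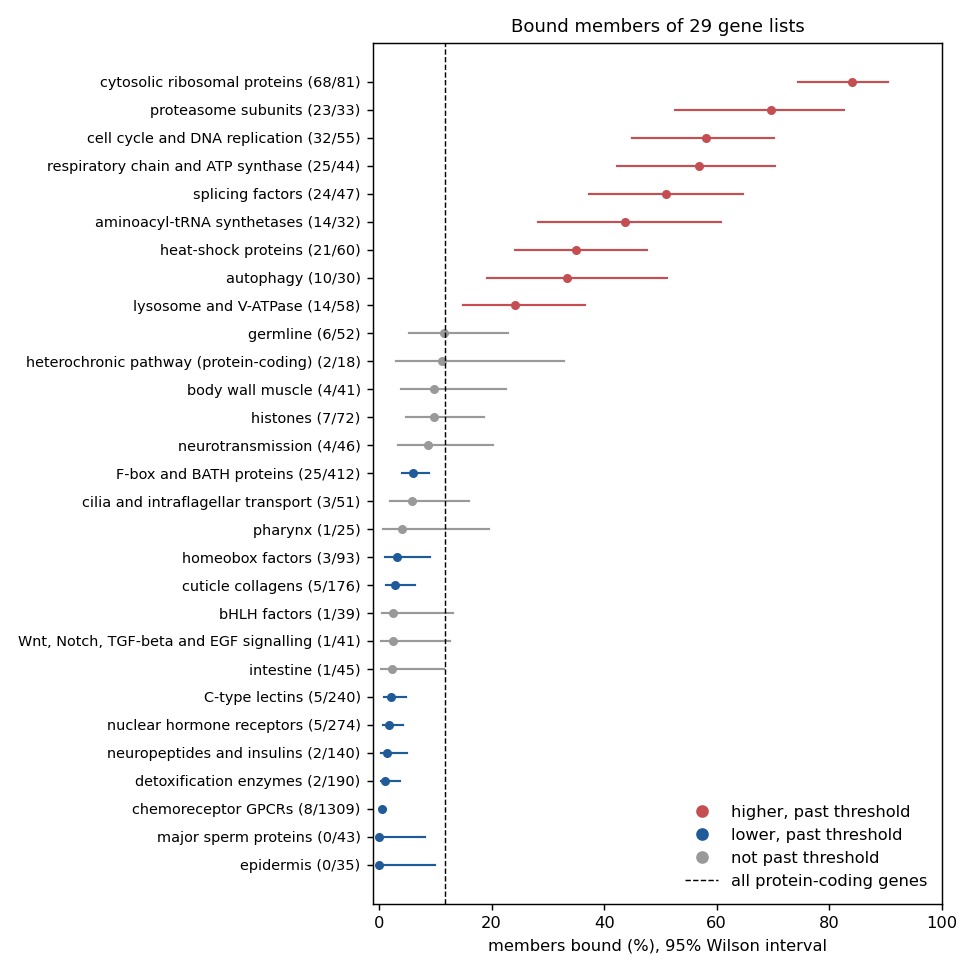
Percent of each gene list's members with a thresholded summit in the promoter window (x axis), with 95% Wilson intervals and the bound and total members beside each name. Red lists were bound more often and blue lists less often than the remaining protein-coding genes after adjustment, grey lists did not pass the threshold, and the dashed line marks 11.8%, the share over all protein-coding genes; ribosomal proteins lie at 84.0% and chemoreceptors at 0.611%.

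Large families of receptors, regulators and enzymes that act in particular tissues or in responses to the environment were bound less often than other genes. Chemoreceptor genes were bound in 8 of 1309 cases (0.611%, odds ratio 0.0427, 0.0213 to 0.0857, adjusted Fisher's exact p = 2.63e-59), with signals of 70.6 at sri-5, 46.5 at srh-170 and 44.5 at sre-1. Nuclear hormone receptor genes were bound in 5 of 274 cases (1.82%, odds ratio 0.137, adjusted Fisher's exact p = 4.74e-09), with 61.8 at nhr-142, 59.96 at nhr-47 and 33.5 at nhr-255. C-type lectin genes were bound in 5 of 240 cases (2.08%, odds ratio 0.157, adjusted Fisher's exact p = 1.55e-07), with 73.1 at clec-53, 46.3 at clec-87 and 31.7 at clec-126. Detoxification enzyme genes were bound in 2 of 190 cases (1.05%, odds ratio 0.0788, adjusted Fisher's exact p = 8.60e-08), at gst-43 (606) and gst-27 (44.9). Neuropeptide and insulin genes were bound in 2 of 140 cases (1.43%, odds ratio 0.108, adjusted Fisher's exact p = 2.04e-05), at nlp-4 (307) and ins-39 (26.2). These 5 lists passed the threshold under every alternative run, with odds ratios from 0.00970 to 0.0727 for chemoreceptors, 0.0989 to 0.214 for nuclear hormone receptors, 0.0563 to 0.236 for lectins, 0.0620 to 0.190 for detoxification enzymes and 0.0647 to 0.283 for neuropeptides and insulins.

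Cuticle collagen genes were bound in 5 of 176 cases (2.84%, odds ratio 0.217, 0.0891 to 0.529, adjusted Fisher's exact p = 6.76e-05). The strongest of these peaks, at col-38 (699), is the same peak that was assigned to rpl-5, which starts on the other side of it, and col-71 (76.7) and col-2 (58.6) followed. F-box and BATH protein genes were bound in 25 of 412 cases (6.07%, odds ratio 0.477, 0.318 to 0.717, adjusted Fisher's exact p = 0.000219), among them fbxb-88 (456) and the neighbours fbxa-11 and fbxa-67, which share a peak (431). Homeobox genes were bound in 3 of 93 cases (3.23%, odds ratio 0.248, 0.0785 to 0.785, adjusted Fisher's exact p = 0.0104), at ceh-38 (73.1), ceh-93 (26.7) and ceh-39 (23.5). None of 43 major sperm protein genes was bound, which allows a share of up to 6.98% (adjusted Fisher's exact p = 0.0125), and none of 35 epidermis genes, which allows up to 8.57% (adjusted Fisher's exact p = 0.0458). The F-box, sperm protein and epidermis calls were lost with the 1091 strongest peaks (odds ratios 0.618, 0.156 and 0.192), and the homeobox call with replicate 2 alone (0.445), while with the 1091 strongest peaks it was kept (0.148). With the nearest 5' end the homeobox, sperm protein and epidermis calls were lost (0.434, 0.111 and 0.587), among genes with any relaxed entry the F-box, sperm protein and epidermis calls (0.627, 0.225 and 0.0914), and with 500 or 2000 bp upstream windows the epidermis call (0.127 and 0.355).

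The 10 remaining lists did not pass the threshold in either direction. Germline genes were bound in 6 of 52 cases (11.5%), among them gld-3 (signal 224) and mes-2 (94.2), and body wall muscle genes in 4 of 41 (9.76%), among them cap-2 (96.6) and cap-1 (31.2). Neurotransmission genes were bound in 4 of 46 cases (8.70%), with a strong peak at the synaptobrevin gene snb-1 (502) and a weaker one at unc-18 (107). Histone genes were bound in 7 of 72 cases (9.72%), among them his-37 (136) and his-72 (94.3). Cilia genes were bound in 3 of 51 cases (5.88%), including dyf-3 (399) and dyf-2 (219), and heterochronic pathway genes in 2 of 18 (11.1%), lin-46 (170.2) and lin-66 (35.4). A single member was bound in the lists named pharynx (sem-5, 84.3, 1 of 25), intestine (erm-1, 37.1, 1 of 45), bHLH factors (hlh-11, 39.8, 1 of 39) and the Wnt, Notch, TGF-beta and EGF pathways (sys-1, 23.2, 1 of 41). Membership was set by gene symbol and does not show where a gene acts. With a 2000 bp upstream window the intestine list passed the threshold as bound less often (odds ratio 0.133), and no other of these lists passed it under the alternatives run. With replicate 1 alone 3 of 72 histone genes were bound (odds ratio 0.328, against 0.805), and among genes with any relaxed entry the odds ratio was 2.48. Cilia genes were bound in 1 of 51 cases with a 500 bp upstream window or the nearest 5' end (odds ratios 0.181 and 0.193, against 0.467) and in 7 with a 2000 bp window (0.934). Over the alternatives the odds ratio ranged from 0.554 to 1.24 for germline, 0.340 to 1.35 for muscle, 0.582 to 1.45 for neurotransmission, 0.533 to 2.77 for heterochronic, 0.244 to 0.568 for pharynx, 0.172 to 0.523 for bHLH and 0.145 to 0.496 for signalling genes.

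Among non-coding RNA genes, those for snoRNAs, which guide RNA modification, lay near thresholded summits most often. A summit was within 500 bp of the 5' end for 66 of 346 snoRNA genes (19.1%), against 10.2% of protein-coding genes (odds ratio 2.07, 1.58 to 2.72, adjusted Fisher's exact p = 2.58e-06). With the 1091 strongest peaks the snoRNA odds ratio was 1.07 and the call was lost. lincRNA genes (9 of 194, odds ratio 0.427, adjusted Fisher's exact p = 0.0143), genes of the ncRNA class (353 of 7764, odds ratio 0.418, adjusted Fisher's exact p = 5.73e-57) and piRNA genes (33 of 15363, odds ratio 0.0189, 0.0134 to 0.0267) were near summits less often. The lincRNA call was lost with 1000 bp on either side (odds ratio 0.632) and kept with 200 bp (0.261) and with the 1091 strongest peaks (2 of 194, 0.164). The piRNA odds ratio was 0.0428 with 1000 bp on either side (93 of 15363), and that of the ncRNA class 0.279 with the 1091 strongest peaks. miRNA genes (19 of 261, odds ratio 0.690) and snRNA genes (13.95% near a summit, odds ratio 1.42) did not pass the threshold. miRNA genes passed it as less often near summits with the 1091 strongest peaks (0.245) and with replicate 2 alone (0.566), and snRNA genes as more often near them with a 200 bp window (2.35).

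For tRNA genes the result turned with the setting. A summit lay within 500 bp of 55 of 612 tRNA genes (8.99%, odds ratio 0.868, 0.655 to 1.15, adjusted Fisher's exact p = 0.343). Within 200 bp it did so for 50 of them, against 5.68% of protein-coding genes, an odds ratio of 1.48 past the threshold. With the 1091 strongest peaks, 5 of 612 tRNA genes were near a summit. The odds ratio was then 0.130, past the threshold as less often near summits (adjusted Fisher's exact p = 2.49e-10, against 0.0154 for the 200 bp result).

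Several 6-base sequences rich in G and C were far more frequent at summits than beside them. ACGCGC, counted on either strand, occurred within the 100 bp centred on the summit in 499 of 2183 peaks (22.9%), against 1.33% of equally long flanks centred 200 bp away (McNemar's exact test, adjusted p = 6.66e-112). CGCGCA occurred in 18.8% against 1.69% (adjusted exact p = 1.10e-82) and GCAAAC in 23.1% against 4.08% (adjusted exact p = 9.42e-78). GACGCA occurred in 19.5% against 2.47% (adjusted exact p = 8.80e-75) and GCGCAC in 15.3% against 1.15% (adjusted exact p = 3.09e-70). These sequences were also more frequent than at the 6581 weaker entries in promoter windows, where ACGCGC reached 3.49% and GCAAAC 5.52%. Within the central 50 bp the shares were lower, 13.9% for ACGCGC, 10.2% for CGCGCA and 12.4% for GACGCA. Of 2080 sequences tested, 654 were more frequent at summits and 596 in flanks, so base composition differed broadly between the 2 places.

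Longer sequences separated more sharply. Of 32381 sequences of 8 bases, 1321 were more frequent at summits and 1020 in flanks. GCAAACAC occurred at 15.6% of summits against 0.412% of flanks, CGCAAACA at 9.89% against 0.183%, GAGACGCA at 9.89% against 0.183% and AGACGCAG at 10.6% against 0.412%. Among the 1091 strongest peaks the share with GCAAAC was 34.9%, against 4.22% of their flanks.

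**Figure D4:**
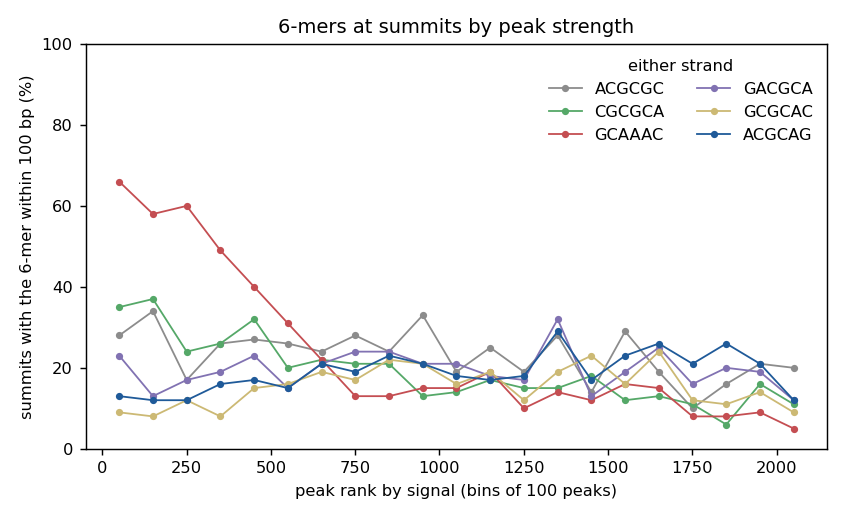
Percent of summits with each 6-base sequence on either strand within the centred 100 bp (y axis), in bins of 100 peaks ordered by signal rank (x axis, strongest at the left). GCAAAC is at 66% in the first bin and 5% in the last full bin. ACGCAG, the reverse complement of CTGCGT, is at 13% and 12% there, and at 29% for ranks 1301 to 1400.

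The tagged gene had a thresholded peak at its own promoter. F16B12.6 lies on the plus strand of chromosome X from 14102316 to 14107913 (ce11), and the peak from 14102121 to 14102259 had its summit at relative position -120 bp, a signal of 159.7 and rank 483. A stronger peak, with rank 432 and signal 197, also lay within 20 kb of the gene. That window held 13 pooled relaxed entries, 0.953 times the genome mean (exact Poisson interval 0.507 to 1.63). It held 27 entries in replicate 1, 1.98 times the mean (1.30 to 2.88), and 16 in replicate 2, 1.17 times (0.670 to 1.90).

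At unc-119, the marker used for rescue in this strain background (chromosome III, 10902641 to 10908935), no thresholded peak lay within 20 kb. The window held 24 pooled relaxed entries, 1.73 times the genome mean (exact Poisson interval 1.11 to 2.58). Chromosome III has many entries throughout, and among windows of this size along it the unc-119 window was at percentile 85.8. The strongest pooled entry there had rank 2275 and signal 20.6. With 10 kb on either side of unc-119 the pooled ratio to the genome mean was 2.29 (1.36 to 3.62). It was then 2.29 in replicate 1 (1.36 to 3.62) and 2.03 in replicate 2 (1.16 to 3.30). With 50 kb on either side the pooled ratio was 1.48 (1.09 to 1.97).

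The same libraries processed on the older assembly ce10 gave nearly the same lists. There were 2177 thresholded peaks on ce10 and 2183 on ce11, and the summed differences in entries per chromosome were 6 for the thresholded, 10 for the pooled, 4 for the replicate 1 and 8 for the replicate 2 list. The highest pooled signal was 1543 on both. The replicate overlap on ce10 was 78.2%.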

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

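Of 351 values computed under alternatives, 307 kept their direction and their side of the threshold or stayed within the tolerance, 22 lost a call, 5 gained one, 13 changed direction and 4 moved. The replicate overlap, promoter share, X chromosome share and the counts of lists and non-coding classes past the threshold kept to these limits under all alternatives run, and between 14 and 19 gene lists passed. The overlap and both shares were judged by their tests and not by their size. The overlap ran from 56.5% with double the number of entries to 85.8% with the 1091 strongest. The promoter share ran from 67.8% with a 500 bp upstream window to 85.5% with the 1091 strongest peaks. The rank correlation of 0.823 was 0.928 among the 1091 strongest peaks and 0.906 as Pearson's r of log2 signal. The share of 56.8% in chromosome centres was no longer past the threshold against protein-coding 5' ends. The count of k-mers past the threshold was 1250 with 6 bases and 2341 with 8, of which more exist. With 1 replicate's list in place of the pooled list, the ratio of entries around F16B12.6 ranged from 1.17 to 1.98.

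Odds ratios that changed direction belonged to lists and classes reported above as not past the threshold, and among them only tRNA genes passed it after the change (1.48 with a 200 bp window). The others were 2.48 for histones and 1.24 for germline genes among genes with any relaxed entry, 1.05 for neurotransmission and 1.17 for heterochronic genes with a 2000 bp window, 1.45, 1.35 and 2.77 for neurotransmission, muscle and heterochronic genes with the nearest 5' end, and 1.10 and 1.14 for germline genes without candidate operon genes and with the 1091 strongest peaks. Leaving out a replicate gave ranges of 0.328 to 0.713 for histones, 0.721 to 1.18 for neurotransmission, 0.848 to 1.05 for muscle and 0.946 to 1.57 for heterochronic genes. The cause was not tested for any of these. No paired analysis was possible because there is 1 group. Unknown read numbers limit what can be said about weak entries.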

Other observations

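The symbol family scan, the fitting of the GCAAAC context, the comparisons with weaker promoter entries, the tests of ribosomal protein peak rank and GCAAAC content, and the test at the F16B12.6 locus were chosen after related results were seen. The shuffles, the distances to the summit, the CTGCGT trend and the isolated gene test were set out before their results. The isolated gene test was set out with the distance from the peak summit, but was run with the distance from the gene's own 5' end. No biological explanation was tested against another group, because the design has 1 group.

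Beyond the fixed lists, all 175 families of genes with a shared symbol and at least 10 members, some of them also in those lists, were compared with the other protein-coding genes. In 25 families the promoters were bound more often and in 24 less often. Nucleoporin genes (npp) were bound in 21 of 26 cases (80.8%, odds ratio 31.7, adjusted Fisher's exact p = 6.30e-14) and translation initiation factor genes (eif) in 17 of 25 (68%, odds ratio 15.998, adjusted Fisher's exact p = 2.34e-09). Mitochondrial ribosomal protein genes were bound in 20 of 41 (mrpl, odds ratio 7.17) and 12 of 29 cases (mrps, odds ratio 5.30). Integrator (ints) and RNA polymerase subunit (rpb) genes were each bound in 7 of 11 cases (63.6%), vesicle sorting genes (vps) in 12 of 31 (38.7%) and TBP-associated factor genes (taf) in 7 of 17 (41.2%), while general transcription factor genes (gtf) were bound in 1 of 10 cases and did not pass the threshold. Among the families bound less often, 15 with 1077 genes in all had no bound member, including the chemoreceptor family str (0 of 193, which allows a share of up to 1.55%), the cytochrome P450 family cyp (0 of 74, up to 4.05%) and the glucuronosyltransferase family ugt (0 of 67, up to 4.48%).

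GCAAAC at the strongest peaks was the first pattern weighed. It was within the central 100 bp of 286 of the 546 strongest summits (52.4%, Wilson interval 48.2 to 56.5%) and of 47 of the 545 weakest (8.62%, 6.55 to 11.3%). Base composition as the whole cause is argued against by the shuffles, since the observed share was 3.97 times the mean of 100 shuffles that kept each sequence's dinucleotides (13.2%, highest 16.1%), and mean G and C content was 45.4% at these summits and 46.8% at the weakest. The share was 9.50 times that of weaker promoter entries, whose mean G and C content was lower (37.7%). It was 8.10 times once these were weighted to the G and C content of the strongest summits. This argues against a feature spread evenly over promoter windows. Weaker entries fell in these windows little more often than the windows cover the genome (23.7% against 21.5%). They need not mark the sites of active promoters, and promoter activity was not measured. A feature spread evenly over promoters with thresholded peaks is argued against by the gene lists. GCAAAC was at 4 of 65 ribosomal protein summits (6.15%, Wilson interval 2.42 to 14.8%) and at 7 of 10 autophagy summits. A feature of some active promoters stays open. Whether the tagged protein or a partner occupies GCAAAC stays open. Its median distance from the strongest summits was 13 bp, but it was chosen as frequent at summits. That choice favours high ratios, such as the 3.97, 9.50 and 8.10 above, and a short distance, by amounts that were not measured. The other 4 sequences chosen so had 20 to 26 bp and ACGCAG 22.5 bp. At the weakest summits GCAAAC had 48 bp, and those 4 sequences had 23 to 36 bp. Around 308 occurrences the next bases were A (90.3%), C (85.7%), C (62.01%) and G (53.6%), and T stood 3 bases before in 80.8%.

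The sequence CTGCGT (ACGCAG on the other strand) did not follow peak strength in the same way. Its share was 13.6% at the 546 strongest summits (Wilson interval 10.9 to 16.7%) and 20.6% at the 545 weakest (17.4 to 24.1%), a ratio of 0.660, while 4.77% of weaker promoter entries held it. Other sequences lay between GCAAAC and CTGCGT. From the strongest to the weakest summits CGCGCA fell from 30.04% to 11.7% and ACGCGC from 26.4% to 16.9%. GACGCA was at 18.9% and 17.98%, and GCGCAC at 11.4% and 13.8%. For GACGCA and for GCGCAC the Wilson intervals at the strongest and weakest summits overlapped. Over these few sequences the changes were therefore graded. Some share most of their bases, as ACGCGC with CGCGCA and GACGCA with ACGCAG, so they are not independent. A split of the sequences into 2 groups was not tested. That the thresholded peaks hold at least 2 kinds of site remains a hypothesis found on these data. It was not tested, because summits with both GCAAAC and CTGCGT were not counted.

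Ribosomal protein promoters were the next pattern. Weak signal near the threshold is argued against by a median rank of 690 among 2183 for their 65 peaks (quartiles 527 and 946). Of genes with no other 5' end within 1000 bp of their own, 17 of 24 ribosomal protein genes were bound (odds ratio 36.0, 14.9 to 87.04). This argues against neighbours that start within that distance as the whole cause. A gene starting further upstream could still own a peak in the window, so this test does not cover such neighbours. With the nearest 5' end 39 of 81 were bound instead of 68, and the odds ratio was 9.16 instead of 40.2, still past the threshold. Neighbours may therefore account for part of the binding. GCAAAC is also argued against as the reason, since it was at 6.15% of these summits (4 of 65, Wilson interval 2.42 to 14.8%), against 17.4% of the peaks ranked 547 to 1092. Low shares were not particular to them: of the peaks at the other lists bound more often, 7.14% held it at aminoacyl-tRNA synthetase, 13.04% at proteasome, 13.6% at splicing, 16% at respiratory, 19.05% at heat-shock, 28.6% at lysosome and 35.5% at cell cycle genes, and 7 of 10 at autophagy genes. High transcription or open chromatin at these promoters stays open, because neither was measured in these samples.

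The third pattern was the excess of relaxed entries around F16B12.6 in replicate 1. There the window was at percentile 99.9 of windows of the same size along the X chromosome, and in replicate 2 at percentile 80.0. Extra copies of the tagged locus could raise the background, and both replicates come from 1 strain, so an excess in both would be needed. The value in replicate 2 lies between what the 2 alternatives predict and does not decide, since a control with the same copies would also remove such an excess and the strain of the control is not given in the sources used here.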
